A study of Salmo salar with 4 samples.

How the data were processed

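Head kidney of Atlantic salmon (Salmo salar), the blood-forming and immune organ of bony fish that also holds steroid-producing interrenal cells, was measured in 4 droplet libraries. Single cells (2 libraries, replicates 3 and 5) came from fresh tissue kept cold, pressed through strainers and collected at the interface of a Percoll density gradient, per the labels' protocols. Single nuclei (2 libraries, replicates 3 and 9) came from flash-frozen tissue minced in a mild Tween buffer and strained, per the labels' protocols. The same 10x Genomics 3' chemistry was used for both, and cells and nuclei were sequenced on different Illumina instruments, per the labels. Only the nuclei samples carry PBS in their titles, and the labels do not say what it stands for or whether those fish were handled otherwise. Method therefore went together with fresh or frozen tissue, the density gradient, the sequencer and that title. The labels do not say whether cell and nucleus replicate 3 came from 1 fish, nor that the 2 nuclei samples came from separate animals, so p-values measure the spread between these samples.

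The authors deposited, for every library, estimated counts of unique molecular identifiers (UMIs) per gene and droplet barcode, in which reads that map to several genes are shared out by expectation maximisation, per the file headers and names. For 3 of the 4 libraries they also deposited whole-number counts of uniquely mapped reads, used here as an alternative. The submitters' processing notes name STARsolo 2.7.10a and Seurat 4.1.0. The genome build and annotation are not given in the sources used here, so no coordinates are printed. The deposited matrices hold all barcodes with no filter on cells. They list 47080 genes by Ensembl identifier, of which 22213 carry a symbol, with 14485 distinct symbols. Symbols come from the deposited gene tables, and a symbol shared by several paralogs is given with its identifier where it is named. Salmon carries many near-identical gene pairs from a genome duplication, so values of single paralogs depend on how shared reads were split.

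Barcodes were called at the larger of 500 UMIs and the steepest point of the barcode rank curve, with at least 200 genes and under 20% mitochondrial UMIs. The unrestricted steepest point fell at ranks of 60256 to 75858, among the empty droplets, where the rule as first fixed would have called every barcode of at least 500 UMIs. The search was therefore limited to above 1.5 times the UMI count at which empty droplets peaked, a limit set after seeing the data, and 500 UMIs was kept as an alternative. Thresholds were 956 and 927 UMIs in cells and 2436 and 1492 UMIs in nuclei. An estimated count of at least 0.5 counted as detection. Doublets were ranked by a simulated-doublet neighbour score (50 neighbours, 2 simulated doublets per barcode) and the expected share of 0.8% per 1000 barcodes was removed, which was 7.05% and 5.06% in cells and 11.0% and 7.55% in nuclei.

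Cells and nuclei were clustered separately with genes z-scored within library, 2000 variable genes, 30 components, 20 neighbours and Leiden resolution 1, which gave 28 clusters of cells and 42 of nuclei. Classes were named only from marker lists fixed before the data were examined, and each name means a class with those markers. Of 954 symbol entries in all lists, 683 matched a gene. The 51 entries written as description phrases could not be used because the files hold no descriptions. The naming rule was set after the cluster tables had been seen. It required at least 3 markers of the list that were detected in at least 10% of the cluster and over 1 higher on the log2 scale than in the other clusters, with 10 CPM added to both. It further required a best competing list, progenitors aside, under 0.75 of the winning score, which summed the log2 differences of the 5 leading markers. No other list could have more markers than the winning one among the 10 leading genes, and the median doublet score could be at most 0.7. The doublet score limit was moved from 0.65 to 0.7. At 0.65 a kidney tubule cluster of nuclei and a dividing phagocyte cluster of cells stayed unnamed, and 0.65 was kept as an alternative. A cluster with less than 1/3 of the median UMI count of its method and no own marker among its leading genes would also have stayed unnamed, which none did for that reason alone. Unnamed clusters held 12.4% and 9.52% of called cells and 34.1% and 13.9% of called nuclei. In cells, 5.22% and 1.93% of barcodes were unnamed for leading genes of another list, 1.36% and 2.01% for a competing list and 5.86% and 5.58% for too few markers. In nuclei the shares were 1.55% and 0.642%, 6.73% and 4.13%, and 22.7% and 9.12%, with a further 3.15% and 0.0459% for the doublet score.

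Estimated counts were summed per library, and per library and class with at least 30 barcodes in each library, then rounded to whole numbers. Cells were compared with nuclei by the edgeR 4.0.16 quasi-likelihood test with TMM normalisation and its default expression filter, two-sided, with Benjamini-Hochberg adjustment at 0.05, on 2 against 2 libraries. Log2 fold changes are cells over nuclei. The SE printed with an edgeR log2 difference is its absolute size divided by the square root of the quasi-likelihood F. The difference of this contrast between granulocytes and B cells was tested as an interaction with library as a block. Fixed gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Alternatives were DESeq2 1.42.0, RLE size factors, no expression filter, other barcode limits, doublets kept, a 10% mitochondrial limit, uniquely mapped reads, thinning to the lowest total, abundant genes left out, other clusterings and each library left out in turn. Added after seeing the data were removal of the mean empty-droplet profile, clusters with at least 90% of barcodes in 1 library left out, unnamed clusters left out, the doublet score limit of 0.65, and library or class totals in place of TMM. CPM printed for single genes beside a log2 difference are scaled to totals times the TMM factor, unless the text says class totals. CPM of marker genes in solid-tissue classes, of gene lists (summed over the members) and of empty droplets are scaled to totals alone. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, and a share of 0 is given with the limit that 3 counts set. Shares and quality measures were compared by an exact two-sided permutation test, which cannot fall below p = 0.333 with 2 against 2 libraries. Genes per barcode were also compared after thinning to 1000 UMIs. A symbol is named where it had an average log2 CPM of at least 5, passed the threshold with no overlap of the groups and was among the 8 largest changes in each direction (4 in each further class, 5 for the class difference), or where it was among the 3 most abundant measured members of a list, with at most 30 symbols for each comparison. No column of another sample was found (0 columns).

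The gene and list tests were tested on simulated data drawn from the real means and library sizes. With all called barcodes summed, 100 genes were changed 2-fold and 100 were changed 4-fold among 33751 tested. Of these edgeR recovered 8% and 83%. It made 18 false calls, 16.5% of its calls, against 68 false calls or 33.7% for DESeq2. The false share depends on how many genes change, so these shares do not carry over to the measured data. For 4-fold changes edgeR recovered 96% in B cells, 90% in granulocytes, 86% in mononuclear phagocytes, 88% in plasma cells, 50% in T cells, 19% in NK cells, 0% in erythroid cells and 100% for the class difference. A simulated list changed 2-fold was called by camera at 0.01 in the sums over all barcodes and in all 7 classes. With an estimated correlation camera called it in none (adjusted p from 0.0905 to 0.325). The fry test called it over all barcodes (adjusted p = 0.0236) and in T cells (0.0436), and missed it elsewhere (0.0835 to 0.220). Genes were simulated independently, so this cannot show whether camera at 0.01 overcalls lists of correlated genes. Clustering used leidenalg and igraph under Python, with scipy and numpy for tests.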

Results

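Transcripts of Atlantic salmon head kidney were counted in 2 libraries of single cells (replicates 3 and 5) and 2 libraries of single nuclei (replicates 3 and 9). The files held 107681198 and 85969377 UMIs in the cell libraries and 134001545 and 82750186 UMIs in the nucleus libraries. Called barcodes numbered 8187 and 6018 cells and 12279 and 8721 nuclei. They held 72.1% and 73.7% of the UMIs of the cell libraries and 40.8% and 35.8% of those of the nucleus libraries. Empty droplets peaked at 245 and 195 UMIs in the cell libraries, which was 4.17% and 2.67% of the median called cell. In the nucleus libraries they peaked at 1288 and 708 UMIs, 34.8% and 26.2% of the median called nucleus. Genes without a symbol held between 45.7% and 51.6% of the UMIs in called barcodes, so the named genes describe about as much of the RNA as they leave out.

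Cells carried far more ribosomal protein messenger RNA than nuclei, and more hemoglobin RNA. Ribosomal protein genes, which encode the protein part of the ribosome, held 14.2% and 13.8% of UMIs in the cell libraries and 1.42% and 2.34% in the nucleus libraries. Hemoglobin genes held 0.276% and 0.451% in cells and 0.0655% and 0.0977% in nuclei. Transcripts of the mitochondrial genome held 4.47% and 3.29% in cells and 0.826% and 3.57% in nuclei, so the groups overlapped. In nucleus replicate 9 the median share was 7.15% in the class of mononuclear phagocytes, against 1.06% in B cells and 1.08% in granulocytes. In the cell libraries B cells had 4.30% and 3.77% and granulocytes 6.56% and 4.00%. The median called cell had 5882 and 7299 UMIs and 2319 and 2533 genes, and the median nucleus 3697 and 2699 UMIs and 2257 and 1633 genes. After thinning to 1000 UMIs the order turned, with 627 and 617 genes in cells and 735 and 710 in nuclei. For each of these measures except the mitochondrial share (p = 0.667), the exact two-sided permutation test of 2 against 2 libraries gave p = 0.333, the smallest it can give.

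The 2 methods were compared first for the cell classes each recovered. Granulocytes, the phagocytes marked here by myeloperoxidase (mpx) and the metalloproteinases mmp9 and mmp13, made up 56.2% and 37.5% of called cells and 6.65% and 15.3% of called nuclei. Leaving out clusters with at least 90% of their barcodes in 1 library moved the difference of the means from 35.8 to 23.1 percentage points. T cells, marked by the transcription factors tcf7 and BCL11B and the receptor subunit cd3e, made up 1.15% and 1.28% of cells and 9.18% and 12.5% of nuclei. A further 1.36% and 2.01% of cells formed an unnamed cluster with 8 T cell markers, among them cd3e, tcf7, zap70 and lck, in which the NK or cytotoxic list scored 0.971 of the T cell list. Erythroid barcodes were 0.867% and 1.30% of cells and 3.45% and 4.59% of nuclei, and thrombocytes, the nucleated clotting cells of fish, 0.489% and 0.349% of cells and 2.65% and 2.90% of nuclei. Plasma cells, marked by irf4b and xbp1, were 2.37% and 4.12% of cells and 1.91% and 1.57% of nuclei. Shares of 3 classes overlapped between the methods. B cells, marked by cd79a and EBF1, were 18.4% and 37.9% of cells and 22.2% and 24.5% of nuclei. Mononuclear phagocytes were 7.41% and 5.92% of cells and 6.85% and 11% of nuclei, and NK or cytotoxic cells, marked by the perforin prf1.3, were 0.708% and 2.09% of cells and 0.937% and 1.63% of nuclei. These are shares of all called barcodes, unnamed ones included. With unnamed clusters left out, plasma cells overlapped too, at 3.63 ± 1.31% of cells and 2.36 ± 0.755% of nuclei (SD, n = 2). Mononuclear phagocytes then did not overlap (7.50 ± 1.36% and 11.6 ± 1.70%), and B cells were 31.5 ± 14.8% and 31.1 ± 3.69%.

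**Figure D1:**
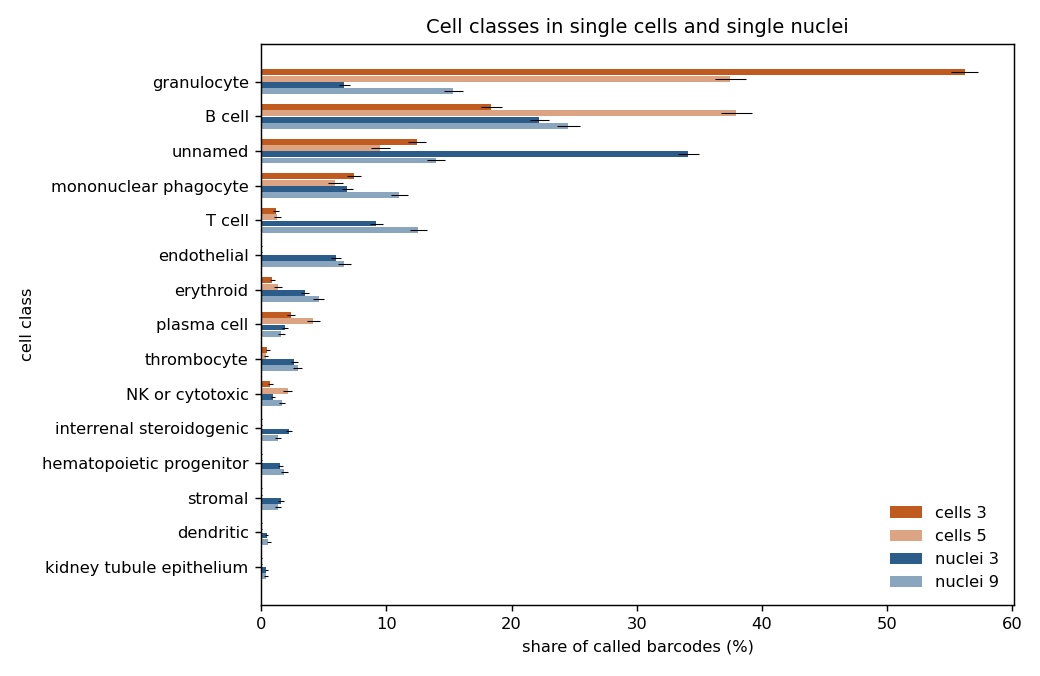
Share of called barcodes in each cell class for the 2 cell libraries and the 2 nucleus libraries. Bars on each value are exact 95% intervals for counting error.

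Solid-tissue classes were named in the nuclei and in 0 cell clusters. Endothelial nuclei made up 5.96% and 6.60% of nuclei and carried the scavenger receptors MRC1, stab1 and stab2, which sinusoidal endothelium uses to take up waste from blood, with MRC1 at 11380 ± 5584 CPM (SD, n = 2 libraries). Stromal nuclei were 1.54% and 1.30%, with cxcl12, the chemokine that holds blood progenitors in their niche, at 6664 ± 47.6 CPM, and with the collagen gene col1a2 and decorin (dcn). Interrenal nuclei, the steroid-producing cells of the fish kidney, were 2.18% and 1.32%, with their regulator nr5a1a at 2689 ± 89.0 CPM and the cholesterol transporter star at 2342 ± 1563 CPM. Blood progenitors marked by myb and fli1a were 1.52% and 1.82% of nuclei, dendritic nuclei marked by flt3 and irf8 were 0.432% and 0.562%, and kidney tubule nuclei marked by the endocytic receptor lrp2a were 0.407% and 0.355%. A count of 0 cells in these classes allows a share of up to 0.0366% and 0.0499% in the 2 cell libraries for counting error alone, and the 0 itself depends on the clustering and the naming rule. Clustering the 4 libraries together put 5.72 ± 4.38% of cells in the progenitor class, 0.903 ± 0.344% in the dendritic, 0.0511 ± 0.0487% in the endothelial and 0.00831 ± 0.0117% in the stromal class (SD, n = 2). It turned the sign of the progenitor and dendritic differences. Leiden resolution 0.5 gave 3.47 ± 2.27% progenitors in cells. In the main clustering an unnamed cluster of 468 cells carried the progenitor markers HLF, fli1a, GFI1, tal1 and MYB. Cells were taken at a Percoll interface, which selects by density, and nuclei were not.

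Unnamed clusters held 12.4% and 9.52% of cells and 34.1% and 13.9% of nuclei, and 1 of them held 2467 nuclei of replicate 3 and 74 of replicate 9. Its mean profile in replicate 3 had a correlation across 14702 genes of 0.959 with the empty droplets of that library, where genes are not independent replicates. Exact Clopper-Pearson 95% intervals reached from 55.1% to 57.3% and from 36.3% to 38.7% for granulocytes in cells, so libraries of 1 method differed by more than counting error. Of the 15 share differences, 12 had no overlap between methods (exact permutation p = 0.333 each), and chance alone gives no overlap in 33.3% of such comparisons. The UMI limit moved many shares: at 500 UMIs most called nuclei were unnamed and the difference for T cells was -0.875 percentage points in place of -9.64.

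Summed over all called barcodes, the named genes with the largest differences toward cells included immediate early genes and an alpha globin, and those toward nuclei included the endothelial markers stab2 and MRC1. The stress-response transcription factor fosab (ENSSSAG00000046644) stood at 81.1 ± 3.99 CPM in cells and 0.171 ± 0.0661 CPM in nuclei (SD, n = 2 libraries each), a log2 difference of 8.97 ± 0.33 (SE; edgeR adjusted p = 0.000522). Its relatives fosb (ENSSSAG00000102772) and JUND (ENSSSAG00000084562) were higher by 7.28 ± 0.37 and 6.36 ± 0.49, and the alpha globin hbaa2 (ENSSSAG00000065229) by 7.77 ± 0.75 on the log2 scale. The calcium-binding pvalb8 (ENSSSAG00000101944) was higher in cells by 7.19 ± 0.43 and the cytokine gene m17 (ENSSSAG00000086976) by 6.06 ± 0.56. In the other direction, complement component c6 had a log2 difference of -8.79 ± 0.58, the calcium channel subunit cacnb2a -8.71 ± 0.30, stab2 -8.40 ± 0.44, MRC1 -8.39 ± 0.88, the transcription factor meis2 -8.10 ± 0.29, the endothelial diaphragm protein plvapb -7.79 ± 0.63, the receptor gpr182 -7.71 ± 0.56 and cxcl12b -7.66 ± 0.26. Every gene named as higher or lower had both libraries of 1 method beyond both of the other.

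Of 35977 genes tested, edgeR called 18808, of which 9586 were higher in cells and 9222 in nuclei. Leaving out any 1 library left from 13333 to 16146 genes. These sums mix the differences within classes with the differences in class shares, and leaving the unnamed clusters out gave 19117 genes. The split between the directions rests on scaling, since TMM factors were 0.596 and 0.608 in the cell libraries and 1.78 and 1.55 in the nucleus libraries. Scaled to library totals, 28436 genes were called, 3424 higher in cells and 25012 in nuclei, and the median log2 difference of all genes went from -0.11 to -1.58.

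Genes of translation, respiration and the early stress response rose together in cells. Among 80 ribosomal protein genes, 74 rose and 1 fell in cells (adjusted over the list alone, 74 and 2), with a median log2 difference of 4.31 and RPS20 at 4.56 ± 0.78. The camera adjusted p was 4.70e-21, and it was 0.550 with an estimated correlation. Among 101 nuclear-encoded genes of oxidative phosphorylation, 92 rose and 2 fell (adjusted over the list alone, 92 and 2), with a median of 3.46 and COX81 at 5.02 ± 0.63 (camera adjusted p = 7.08e-21, and 0.550 with an estimated correlation). Among 66 immediate early genes, 62 rose and 2 fell (adjusted over the list alone, 62 and 2), with a median of 3.36 and the inflammatory regulator cebpb (ENSSSAG00000122018) at 4.55 ± 0.55 (camera adjusted p = 1.00e-17, and 0.550 with an estimated correlation). The 29 interferon-stimulated genes had 22 higher and 2 lower (adjusted over the list alone, 23 and 2), with a median of 2.14 and the signal transducer stat1a (ENSSSAG00000073567) at 2.25 ± 0.23 (camera adjusted p = 1.18e-06, and 0.550 with an estimated correlation). Among 39 heat shock genes 23 rose and 5 fell (adjusted over the list alone, 25 and 5), with a median of 1.44 and the chaperone hspa8 at 3.47 ± 0.62 (camera adjusted p = 0.000263, and 0.451 with an estimated correlation). The 55 cell cycle genes had 35 higher and 4 lower (adjusted over the list alone, 35 and 5), with a median of 1.64 and the chromatin protein hmgb2a (ENSSSAG00000054548) at 4.53 ± 0.61 (camera adjusted p = 5.06e-06, and 0.576 with an estimated correlation).

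**Figure D2:**
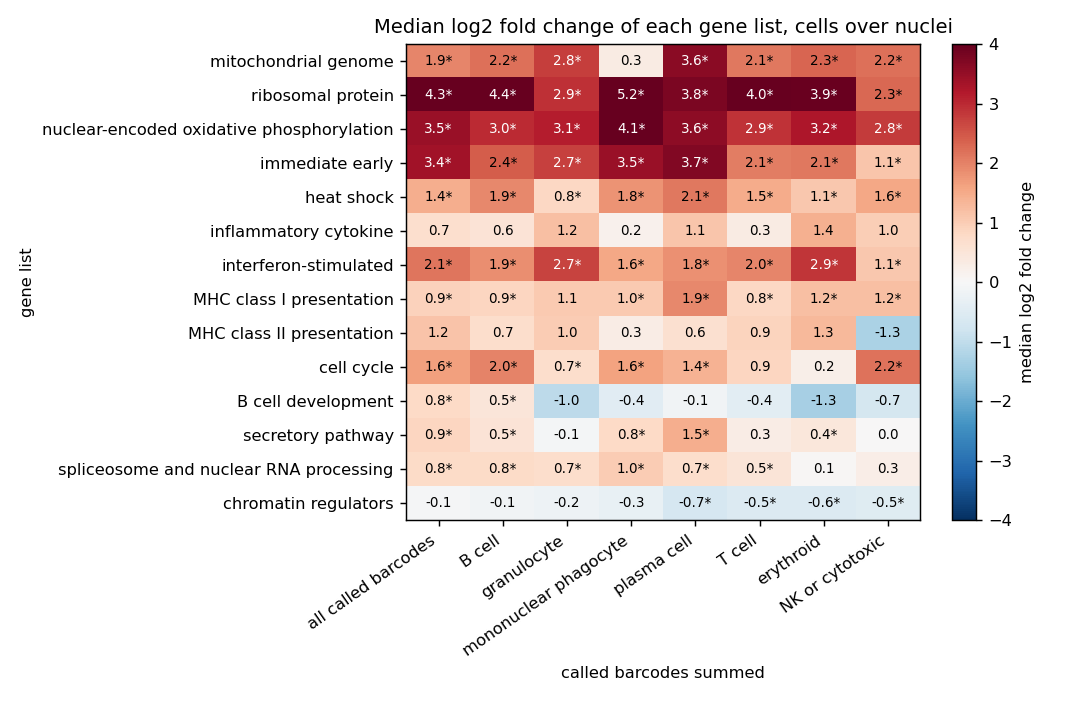
Median log2 difference, cells over nuclei, of 14 gene lists over all called barcodes and in 7 cell classes. An asterisk marks a camera adjusted p under 0.05 at a preset correlation of 0.01, and colors stop at 4 in both directions.

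Smaller shifts toward cells, relative to all other genes and with TMM scaling, were called for secretion, splicing and antigen presentation. Of 56 secretory pathway genes 30 rose and 2 fell (adjusted over the list alone, 33 and 3; median 0.86), led in abundance by the translocon subunit sec61b at 5.12 ± 0.46 (camera adjusted p = 3.02e-05, and 0.576 with an estimated correlation). Of 60 splicing genes 35 rose and 3 fell (adjusted over the list alone, 35 and 3; median 0.76), with srrm1 (ENSSSAG00000064210) at 1.16 ± 0.23 (camera adjusted p = 3.01e-06, and 0.451 with an estimated correlation). Of 21 genes of MHC class I presentation, which show peptides from inside the cell to T cells, 10 rose and 2 fell (adjusted over the list alone, 10 and 2; median 0.92; camera adjusted p = 0.00613, and 0.576 with an estimated correlation). Of 43 B cell development genes 20 rose and 4 fell (adjusted over the list alone, 20 and 5; median 0.80; camera adjusted p = 0.0417, and 0.576 with an estimated correlation), and cd79a had 0.43 ± 0.45 (edgeR adjusted p = 0.449). The B cell development call ended without cell replicate 5, nucleus replicate 3 or nucleus replicate 9 (camera adjusted p = 0.153, 0.0505 and 0.0953). Of the 13 mitochondrial genome genes 1 rose and 0 fell in edgeR (adjusted over the list alone, 0 and 0), with a median of 1.94. The camera adjusted p was 0.0109, and 0.576 with an estimated correlation. DESeq2 called 10 of these genes as higher in cells and 0 as lower. In simulated data over all barcodes it made 68 false calls against 18 for edgeR, a comparison made with few changed genes. The 24 inflammatory cytokine genes had 10 higher and 4 lower (adjusted over the list alone, 11 and 4; median 0.67; camera adjusted p = 0.0707), with irf1 at 1.80 ± 0.32, and passed without nucleus replicate 9 (0.0344). The 5 genes of MHC class II presentation had 3 higher and 0 lower (adjusted over the list alone, 3 and 0; median 1.15; camera adjusted p = 0.142), with the antigen-processing reductase ifi30 (ENSSSAG00000077221) at 1.89 ± 0.50. The 106 chromatin regulators had 20 higher and 18 lower (adjusted over the list alone, 18 and 15; median -0.06; camera adjusted p = 0.969), with the remodeller chd2 (ENSSSAG00000040358) at 1.00 ± 0.29. Without cell replicate 3 the single-gene calls for srrm1, ifi30 and chd2 ended (edgeR adjusted p = 0.0680, 0.0672 and 0.138), and without cell replicate 5 those for ifi30 and chd2 (edgeR adjusted p = 0.0619 and 0.185). In all, 11 of 14 lists passed camera, 6 passed fry and 0 passed with an estimated correlation (camera, 0 at an unadjusted p under 0.05). That form of camera also missed a simulated 2-fold list (adjusted p = 0.0905). The simulated genes were independent, so this does not show whether the preset correlation overcalls lists of correlated genes.

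The direction of several lists turned when counts were scaled to library totals in place of TMM. Ribosomal proteins (median 2.87, 73 higher and 5 lower in cells), oxidative phosphorylation (2.01, 82 and 9), immediate early (1.90, 50 and 5) and interferon-stimulated genes (0.68, 15 and 6) stayed higher in cells. The mitochondrial genome median was 0.54 with 0 genes called in either direction. Cell cycle genes (0.19, 16 and 19) and heat shock genes (0.00, 11 and 12) had no clear direction. Splicing (-0.72, 6 and 31), secretory pathway (-0.60, 9 and 28), B cell development (-0.67, 5 and 20), MHC class I (-0.51, 8 and 8), MHC class II (-0.33, 1 and 2) and inflammatory cytokine genes (-0.81, 4 and 13) had medians toward nuclei. Chromatin regulators had a median of -1.54, with 3 higher and 92 lower. Camera compares a list with all other genes, so 11 lists passed on this scale too, without B cell development (camera adjusted p = 0.0556) and with chromatin regulators toward nuclei (0.0493). The single genes srrm1 and chd2 turned, to -0.31 and -0.46, and irf1 and ifi30 no longer passed (edgeR adjusted p = 0.265 and 0.305).

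Markers of endothelium, stroma, interrenal tissue and T cells were mostly higher in nuclei. Among 52 endothelial markers 43 were higher in nuclei and 3 in cells (adjusted over the list alone, 43 and 3). For the 38 stromal markers the numbers were 32 and 0 (adjusted over the list alone, 32 and 1), for 13 interrenal markers 11 and 0 (adjusted over the list alone, 11 and 0), and for 25 T cell markers 19 and 2 (adjusted over the list alone, 20 and 2). Toward nuclei there were also 17 of 28 mural markers against 1, 19 of 39 kidney tubule markers against 1, 10 of 20 chromaffin markers against 1 and 9 of 16 dendritic markers against 2. Adjusted over the list alone these were 18 and 1, 20 and 2, 10 and 1, and 9 and 3. Markers of podocytes (6 of 13 against 1), pigment cells (6 of 12 against 1), glia (5 of 11 against 1), thrombocytes (7 of 17 against 3), mononuclear phagocytes (12 of 34 against 6), erythroid cells (8 of 19 against 5) and progenitors (11 of 30 against 7) also had more members higher in nuclei. Adjusted over the list alone these were 6 and 1, 7 and 1, 5 and 1, 9 and 3, 13 and 6, 8 and 6, and 11 and 7. Toward cells there were 10 of 15 plasma cell markers against 0, 10 of 19 granulocyte markers against 4 and 7 of 17 B cell markers against 0 (adjusted over the list alone, 11 and 0, 11 and 4, and 6 and 0). The 16 NK or cytotoxic markers had 3 in each direction by either adjustment. Scaled to library totals, 5 plasma cell markers were higher in nuclei against 2, 7 B cell markers against 1, 10 NK or cytotoxic markers against 1 and 5 granulocyte markers against 8 higher in cells.

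Within B cells, AP-1 factors and the calcium-binding pvalb8 were higher in cells, while transcripts of endothelial, stromal and interrenal cells were higher in nuclei. The log2 difference was 7.55 ± 0.33 for pvalb8 (ENSSSAG00000101944; 411 ± 45.9 against 2.22 ± 0.307 CPM, SD, n = 2), 6.12 ± 0.27 for fosb (ENSSSAG00000102772), 5.38 ± 0.34 for JUND (ENSSSAG00000084562), 5.23 ± 0.46 for the histone variant H2AZ1 (ENSSSAG00000039934) and 5.17 ± 0.74 for rps14. The genes furthest toward nuclei were MRC1 at -8.88 ± 0.36, the complement protease cfd at -7.57 ± 0.54, star (ENSSSAG00000068626) at -7.49 ± 0.31, c6 at -7.48 ± 0.30, cxcl12b at -6.32 ± 0.36 and cxcl12 at -5.00 ± 0.27 (edgeR adjusted p from 0.000462 to 0.000465 for these 6 genes). All 6 were also in the empty droplets of the nucleus libraries, with MRC1 at 1673 CPM, cfd at 1349, cxcl12 at 806, c6 at 385, star at 369 and cxcl12b at 305. Of the 76 endothelial, stromal and interrenal markers measured in B cells, 62 were higher in nuclei, and all 62 were at a higher level in the empty droplets of nuclei than of cells. Carboxypeptidase cpn1, at -4.67 ± 0.24, had -1.22 ± 1.25 (SE; edgeR adjusted p = 0.460) once the mean empty-droplet profile was removed.

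**Figure D3:**
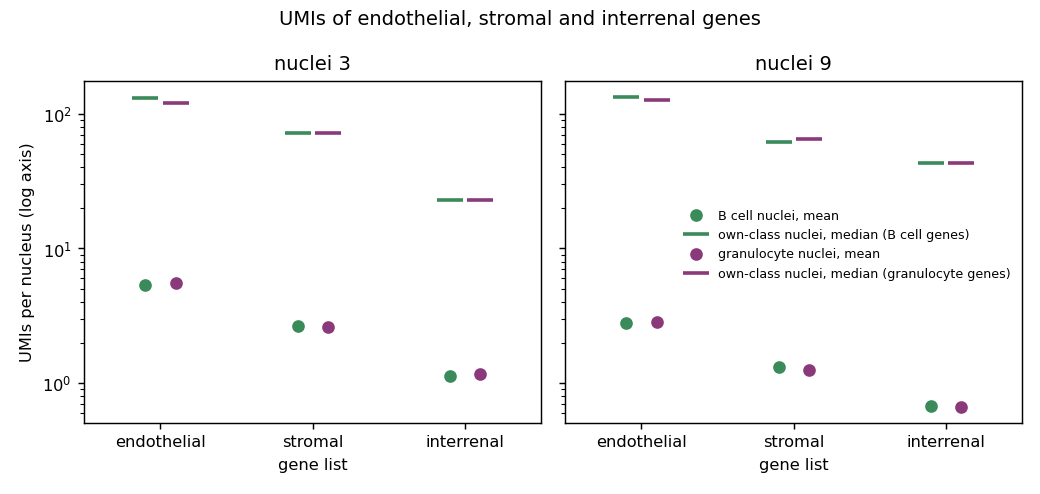
UMIs of endothelial, stromal and interrenal marker genes per nucleus in B cells and granulocytes (points) and in nuclei of the class the markers belong to (lines), in the 2 nucleus libraries. Each class uses its own set of tested genes.

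In B cells edgeR called 12603 of 27505 genes, 6905 higher in cells and 5698 in nuclei. Without cell replicate 3 the number was 8290, without cell replicate 5 it was 7528, and with uniquely mapped reads of 3 libraries it was 7773. Of 14 gene lists 11 passed camera, all toward cells, among them ribosomal proteins (74 of 79 higher and 0 lower, adjusted over the list alone 74 and 0, median 4.37), immediate early genes (49 of 62 and 6 lower, adjusted over the list alone 49 and 6, median 2.42) and cell cycle genes (36 of 51 and 1 lower, adjusted over the list alone 38 and 2, median 1.98). With an estimated correlation 0 lists passed in B cells (1 at an unadjusted p under 0.05, and 8 with fry), and these 3 had adjusted p = 0.497, 0.444 and 0.497 (camera). The receptor subunit cd79a did not pass in B cells, at 0.47 ± 0.39 (edgeR adjusted p = 0.358). Scaled to class totals, it stood at 1075 ± 100 CPM in cells and 1857 ± 172 CPM in nuclei (SD, n = 2), a log2 difference of -0.79 (edgeR adjusted p = 0.0924). On that scale 20815 genes were called, 2693 higher in cells, and the 3 lists kept their direction (medians 3.11, 1.15 and 0.72). B cell development genes turned from a median of 0.47 to -0.79 (camera adjusted p = 0.0562), secretory pathway genes from 0.54 to -0.72 and splicing genes from 0.75 to -0.51.

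Within granulocytes, immediate early and interferon-stimulated genes were higher in cells, and many of the transcripts higher in nuclei were those seen in B cells. The antiviral ubiquitin-like gene isg15 was higher in cells by 6.51 ± 0.38 on the log2 scale (92.4 ± 10.0 against 0.987 ± 0.600 CPM, SD, n = 2), the interferon-induced ifit9 (ENSSSAG00000068365) by 4.84 ± 0.42 and cebpb (ENSSSAG00000122018) by 4.37 ± 0.48. The cytokine gene m17 (ENSSSAG00000086976) was higher by 6.87 ± 0.40, the actin regulator marcksl1b (ENSSSAG00000045029) by 6.31 ± 0.50, the peroxisome gene pex11a by 6.22 ± 0.83 and the glycolytic tpi1b (ENSSSAG00000043281) by 6.20 ± 0.49. For fosab (ENSSSAG00000046644) there were 3093 counts in cells and 3 in nuclei, a ratio of 399 with TMM scaling (95% counting interval 136 to 1937) and of 186 with class totals (63.5 to 902). Toward nuclei stood MRC1 at -9.30 ± 0.71, star (ENSSSAG00000068626) at -8.20 ± 0.32, c6 at -7.89 ± 0.45, cxcl12b at -7.03 ± 0.35, cfd at -6.44 ± 1.14 and cxcl12 at -4.86 ± 0.29 (edgeR adjusted p from 0.000336 to 0.00428 for these 6 genes). The empty droplets of nuclei held these 6 genes at 305 to 1673 CPM.

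In granulocytes edgeR called 12736 of 26185 genes, 6902 higher in cells and 5834 in nuclei. Of 14 lists 8 passed camera, all toward cells. Interferon-stimulated genes had 19 of 25 higher and 2 lower (adjusted over the list alone, 19 and 2; median 2.7; camera adjusted p = 4.56e-06, and 0.529 with an estimated correlation). Immediate early genes had 45 of 58 higher and 3 lower (adjusted over the list alone, 45 and 3; median 2.73; camera adjusted p = 1.08e-11, and 0.529 with an estimated correlation). Genes of the mitochondrial genome had 10 of 13 higher and 0 lower (adjusted over the list alone, 12 and 0; median 2.76; camera adjusted p = 0.00131, and 0.648 with an estimated correlation), and the call for COX2 ended without cell replicate 3 or 5 (edgeR adjusted p = 0.0919 and 0.0619). B cell development genes had 9 of 37 higher and 19 lower (adjusted over the list alone, 9 and 19; median -1.05; camera adjusted p = 0.0659). That list passed toward nuclei without cell replicate 3 (camera adjusted p = 0.0387), cell replicate 5 (0.0185) or nucleus replicate 9 (0.0294). With class totals in place of TMM, 3141 genes were higher in cells and 14623 in nuclei, and the interferon, immediate early and mitochondrial genome lists kept medians of 1.59, 1.61 and 1.72.

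Within mononuclear phagocytes, the macrophage receptor gene MARCO was far higher in nuclei and the FOS genes were far higher in cells. Scaled to class totals, MARCO stood at 4.38 ± 2.36 CPM in cells and 1261 ± 924 CPM in nuclei (SD, n = 2), and on the same scale at 188 CPM in the empty droplets of nuclei and 24.0 CPM in those of cells, above its level in the called cells. With TMM scaling its log2 difference was -6.82 ± 0.87. The scaffold gene sash1 had -8.65 ± 0.35, cfd -7.84 ± 0.54 and the adhesion gene CNTN1 (ENSSSAG00000072055) -6.49 ± 0.41. Empty droplets of nuclei held cfd too, at the level given for B cells. The 2 fosb paralogs had 8.70 ± 0.55 (ENSSSAG00000082224) and 8.05 ± 0.46 (ENSSSAG00000102772), and the 2 fosab paralogs 7.62 ± 0.35 (ENSSSAG00000046644) and 7.55 ± 0.53 (ENSSSAG00000109807). The lysosomal reductase ifi30 (ENSSSAG00000077221) was higher in cells by 2.42 ± 0.64, and the chemokine CCL19 did not pass at -0.17 ± 0.57 (edgeR adjusted p = 0.813). Without nucleus replicate 9, CCL19 had 1.12 (edgeR adjusted p = 0.00331), and without nucleus replicate 3 it had -0.88 (0.00720). Its value scaled to class totals was -1.52 (edgeR adjusted p = 0.00561). Without cell replicate 5 the call for ifi30 ended (edgeR adjusted p = 0.0528). edgeR called 13533 of 24758 genes, 7206 higher in cells and 6327 in nuclei, and 8962 without cell replicate 3. Class totals in place of TMM gave 2982 higher in cells and 15890 in nuclei. Of 14 lists 9 passed camera, with ribosomal proteins at a median of 5.22 (74 of 78 higher, 0 lower, adjusted over the list alone 74 and 0) and immediate early genes at 3.45 (53 of 61 higher, 3 lower, adjusted over the list alone 54 and 4). With an estimated correlation 0 passed (0 at an unadjusted p under 0.05, and 9 with fry), and these 2 had adjusted p = 0.459 and 0.399 (camera). The mitochondrial genome list had 0 of 13 genes passing in either direction in edgeR (adjusted over the list alone, 0 and 0), none at an unadjusted p under 0.05, and 0 with DESeq2. Its median was 0.34 (camera adjusted p = 0.515), and without nucleus replicate 9 the list passed toward cells (camera adjusted p = 0.000726). The median scaled to class totals was -0.96, with 4 genes higher in nuclei, while ribosomal proteins and immediate early genes kept medians of 3.81 and 2.06. The median mitochondrial share of UMIs in phagocyte nuclei was 0.752% in replicate 3 and 7.15% in replicate 9.

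Within plasma cells, the antibody-secreting class, immediate early genes were again higher in cells, and more chromatin regulators were lower than higher there, although most did not pass. The AP-1 genes fosb (ENSSSAG00000102772; 718 counts) and fosab (ENSSSAG00000109807; 547 counts) had 0 counts in nuclei, so they were at least 166-fold and 126-fold higher in cells with TMM scaling, and at least 55.6-fold and 42.3-fold with class totals, against a floor of 3 counts over the group. The phosphatase dusp1 had 587 counts against 1, a TMM-scaled ratio of 407 (95% counting interval 72.8 to 16105; 136 with class totals), and fosb (ENSSSAG00000082224) 880 against 2, a ratio of 305 (84.2 to 2523; 102 with class totals). The 46 immediate early genes had 38 higher and 2 lower in cells (adjusted over the list alone, 38 and 2; median 3.70, and 3.67 with 4 genes at their bound; camera adjusted p = 5.10e-12, and 0.339 with an estimated correlation). Toward nuclei, cfd had 615 counts against 3 in cells, a TMM-scaled ratio of 296 (101 to 1437; 883 with class totals). The growth-arrest gene btg2 was higher in cells by 6.67 ± 0.74 on the log2 scale (1915 ± 262 against 20.0 ± 13.5 CPM, SD, n = 2). MRC1 had -7.86 ± 0.52 and cxcl12 -6.73 ± 0.45. The empty droplets of nuclei held MRC1 at 1673 CPM, cxcl12 at 806 CPM and cfd at the level given for B cells. Differences of MRC1, cxcl12 and cfd therefore do not show expression in plasma cell nuclei. The 100 chromatin regulators had 8 higher and 35 lower in cells (adjusted over the list alone, 8 and 35; median -0.66; camera adjusted p = 0.000292, and 0.382 with an estimated correlation), with 57 not passing and fry at an adjusted p of 0.0506, while chd2 (ENSSSAG00000040358) had 1.00 ± 0.38 (edgeR adjusted p = 0.0524), and passed without nucleus replicate 3 (0.0408) or 9 (0.0110). The 56 secretory pathway genes had 34 higher and 1 lower (adjusted over the list alone, 36 and 2; median 1.46; camera adjusted p = 8.62e-06, and 0.581 with an estimated correlation). All 12 genes of the mitochondrial genome measured were higher in cells in edgeR (adjusted over the list alone, 12; median 3.60; camera adjusted p = 4.88e-07, and 0.339 with an estimated correlation), and 11 with DESeq2. The calls for COX2 and COX3 of this list ended without cell replicate 3 (edgeR adjusted p = 0.151 and 0.0615) or 5 (0.150 and 0.0682). edgeR called 7763 of 16395 genes, 4290 higher in cells and 3473 in nuclei. DESeq2 called 4243, with 69.4% of them higher in cells in place of 55.3%. Of 14 lists 11 passed camera, 8 passed fry and 0 passed with an estimated correlation (camera, 2 at an unadjusted p under 0.05). When scaled to class totals, 1528 genes were higher in cells and 10233 in nuclei, the secretory pathway median was -0.10 (12 higher and 15 lower), and the immediate early and mitochondrial genome medians were 2.09 and 2.07.

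Within T cells, ribosomal protein genes were higher in cells and the transcription factor FOXO1 was lower. The log2 difference was 4.78 ± 0.65 for rps14, 4.69 ± 0.42 for the proteasome assembly gene psmg4 and -1.81 ± 0.35 for FOXO1 (155 ± 19.7 against 541 ± 4.96 CPM, SD, n = 2). Of the genes furthest toward nuclei, c6, star (ENSSSAG00000068626), the adenylate cyclase adcy2b and stab1 had 0 counts in the T cells of the cell libraries. Against a floor of 3 counts over the group they were at least 27.2-fold, 26.3-fold, 20.8-fold and 19.7-fold lower in cells with TMM scaling, and at least 50.4-fold, 48.6-fold, 38.5-fold and 36.5-fold with class totals, and the empty droplets of nuclei held them at 385, 369, 273 and 313 CPM. Without nucleus replicate 9 these 4 genes and FOXO1 did not pass (edgeR adjusted p from 0.0884 to 0.102), and without cell replicate 5 neither did FOXO1 (0.0755) and adcy2b (0.0718; edgeR). The 76 ribosomal protein genes had 74 higher and 0 lower (adjusted over the list alone, 74 and 1; median 3.97; camera adjusted p = 7.85e-37, and 0.521 with an estimated correlation). The 22 interferon-stimulated genes had 14 higher and 0 lower (adjusted over the list alone, 16 and 1; median 1.95; camera adjusted p = 1.38e-07, and 0.521 with an estimated correlation). The 103 chromatin regulators had 1 higher and 5 lower (adjusted over the list alone, 0 and 1; median -0.54; camera adjusted p = 0.00460, and 0.521 with an estimated correlation), a call that ended without cell replicate 3 (0.0905). edgeR called 3847 of 17327 genes, 2557 higher in cells and 1290 in nuclei. The number was 1653 without cell replicate 5, 1575 without nucleus replicate 3, 240 without nucleus replicate 9 and 2129 after thinning to the lowest total, and the class had 94 and 77 cells. On the scale of class totals edgeR called 8601 genes, 1565 higher in cells, and the ribosomal protein and interferon medians were 3.08 and 1.05.

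Within erythroid cells, hemoglobin held 28.3% and 39.7% of UMIs in cells and 0.218% and 1.09% in nuclei. The alpha globin hbaa2 (ENSSSAG00000065229) was higher in cells by 12.79 ± 3.55 on the log2 scale and the stress-induced ddt4l by 8.74 ± 0.73. The hbaa2 call ended without any 1 of cell replicate 3, cell replicate 5 or nucleus replicate 9 (edgeR adjusted p = 0.241, 0.0888 and 0.0512). The axon guidance genes plxna2 and robo3, the adenosine kinase adkb and the cadherin cdh24b had 0 counts in cells and were at least 22.9-fold, 22.2-fold, 20.0-fold and 14.5-fold lower there with TMM scaling, and at least 121-fold, 116-fold, 105-fold and 76.2-fold with class totals, against a floor of 3 counts over the group. Their levels in the empty droplets of nuclei were 25.2, 13.7, 13.5 and 5.85 CPM. The 75 ribosomal protein genes had 71 higher and 0 lower (adjusted over the list alone, 72 and 1; median 3.95; camera adjusted p = 4.81e-33, and 0.433 with an estimated correlation). The 17 interferon-stimulated genes had 13 higher and 0 lower (adjusted over the list alone, 13 and 1; median 2.86; camera adjusted p = 1.11e-06, and 0.433 with an estimated correlation). edgeR called 3157 of 13439 genes, 1951 higher in cells and 1206 in nuclei. Without nucleus replicate 3 it called 1604, and without nucleus replicate 9 it called 0, with 2911 genes at an unadjusted p under 0.05, where the lone sample is assumed to vary like the other group. Scaled to class totals, 353 genes were higher in cells and 10786 in nuclei, ribosomal protein genes had a median of 1.52 (27 higher and 3 lower) and interferon-stimulated genes one of 0.29 (3 and 4).

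Within NK or cytotoxic cells, the signalling regulator rgs13 (ENSSSAG00000092028) was higher in cells by 5.67 ± 0.58 on the log2 scale (457 ± 2.90 against 8.75 ± 1.18 CPM, SD, n = 2) and the replication protein rpa3 (ENSSSAG00000070483) by 5.55 ± 0.69. The mitochondrial acyl carrier ACPM had 55 counts against 1 in nuclei, a TMM-scaled ratio of 77.3 (95% counting interval 13.3 to 3107; 62.9 with class totals), and atp5l 49 against 2, a ratio of 34.4 (9.03 to 292; 28.0 with class totals). The genes cxcl12b, star and GP182 had 0 counts in cells and were at least 31.8-fold, 28.5-fold and 18.5-fold lower there with TMM scaling, and at least 39.1-fold, 35-fold and 22.7-fold with class totals, against a floor of 3 counts over the group. For cfd there were 490 counts in nuclei and 1 in cells, a TMM-scaled ratio of 349 (62.3 to 13803; 429 with class totals). The empty droplets of nuclei held cxcl12b at 305 CPM, star at 369 CPM and cfd at the level given for B cells. Counts of cxcl12b, star and cfd therefore do not show expression in NK or cytotoxic nuclei. The 31 cell cycle genes had 22 higher and 0 lower (adjusted over the list alone, 23 and 0; median 2.17; camera adjusted p = 3.60e-08, and 0.490 with an estimated correlation). edgeR called 2400 of 7462 genes, 1406 higher in cells and 994 in nuclei. The number was 1575 without cell replicate 5, 1133 without nucleus replicate 3, 1408 with DESeq2, 1486 with uniquely mapped reads of 3 libraries and 4115 at a Leiden resolution of 2. Medians of all lists in every class are in the plot of list medians.

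The contrast of cells with nuclei differed between granulocytes and B cells. These were the shared classes with the most barcodes in their smallest library (816 and 1504), although in nucleus replicate 3 T cells (1127) and mononuclear phagocytes (841) outnumbered granulocytes. The coagulation inhibitor tfpi2 (ENSSSAG00000069027) had a log2 contrast of 5.25 in granulocytes and -1.97 in B cells, a difference of 7.39 ± 0.41 (SE; edgeR adjusted p = 3.21e-06). The formyl peptide receptor fpr1 (ENSSSAG00000002856) had 3.56 and -1.60, marcksl1b (ENSSSAG00000045029) 6.31 and 0.11, m17 (ENSSSAG00000086976) 6.87 and 1.06, and the actin-binding thymosin tmsb1 (ENSSSAG00000068011) 5.82 and 0.09. In the other direction, the heat shock gene hsp90aa1.2 (ENSSSAG00000042708) had -1.69 in granulocytes and 4.03 in B cells, zgc:194275 -2.25 and 2.83, the differentiation inhibitor id3 (ENSSSAG00000107585) -3.95 and 1.12, the receptor gpr184 (ENSSSAG00000090885) -4.32 and 0.54 and TMCC3 (ENSSSAG00000009291) -2.86 and 1.81. edgeR called 5893 of 29998 genes, 3481 with a higher contrast in granulocytes and 2412 with a higher one in B cells. The number was 1562 after removal of the empty-droplet profile, 3488 without nucleus replicate 3, 3379 with DESeq2 and 3845 after thinning to the lowest total.

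Levels of gene lists across the 7 classes with at least 30 barcodes in each library were compared without a test, since the classes come from the same data. They are scaled to class totals. Secretory pathway genes were highest in plasma cells in 4 of 4 libraries, at 6868 ± 434 CPM in cells and 4973 ± 2732 CPM in nuclei (SD, n = 2), and 19 of 21 pairs of classes kept 1 order in all 4. The secretory pathway list has the entry ssr4 in common with the markers that name plasma cells, so its place may be partly built in. B cell development genes were highest in B cells in 4 libraries (5781 ± 526 CPM in cells and 10165 ± 287 CPM in nuclei), with 13 of 21 pairs in 1 order. That list shares cd79a, ebf1 and blnk, among others, with the markers that name B cells, so its place there is partly built in. Splicing genes had a lower mean in cells than in nuclei in all 7 classes, among them B cells (3315 ± 76.6 and 4175 ± 315 CPM) and plasma cells (2057 ± 121 and 3699 ± 705 CPM). MHC class II presentation genes were highest in mononuclear phagocytes in 4 libraries (326 ± 14.8 and 188 ± 105 CPM), with 12 of 21 pairs in 1 order. The MHC class II list shares lgmn with the markers that name mononuclear phagocytes, so this place is partly built in too. Oxidative phosphorylation genes kept 1 order in 2 of 21 pairs. Immediate early genes in cells were highest in granulocytes, at 7519 ± 584 CPM, and in nuclei those granulocytes had 1366 ± 200 CPM.

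**Figure D4:**
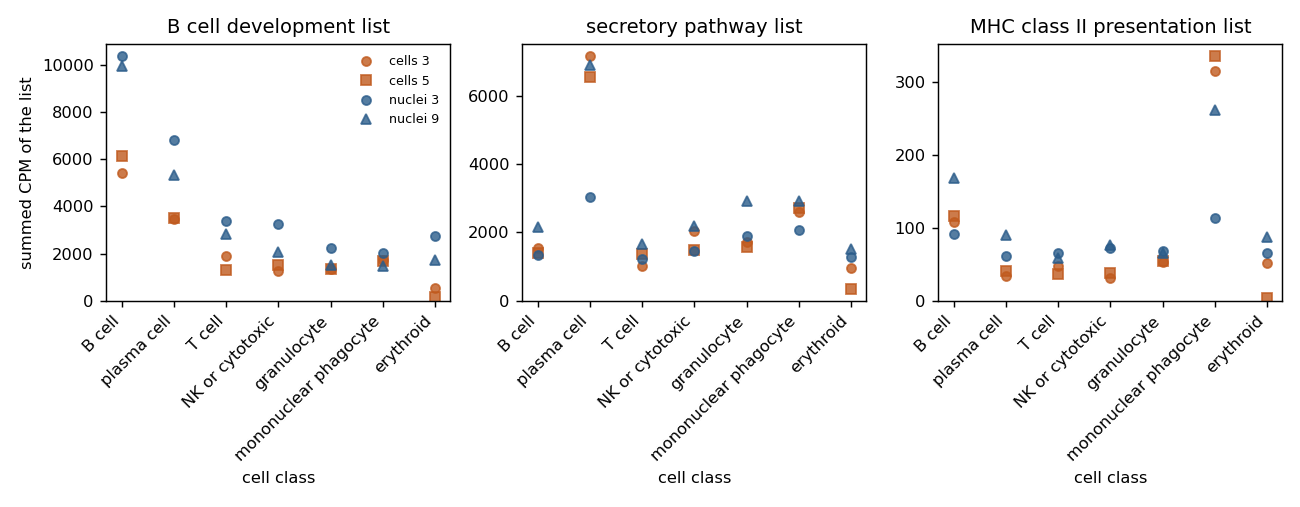
Summed CPM of 3 gene lists in the 7 classes with at least 30 barcodes in each library. Each point is 1 library.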

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

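The tests of the difference between classes, of class makeup, of handling and of free RNA by removal were chosen only after the result was seen, and removal of the empty-droplet profile and scaling to library totals were alternatives added after the data were examined. The contrast of cells with nuclei differed between granulocytes and B cells for 10 named genes by a test of the difference itself (edgeR interaction term). Granulocytes had the higher log2 contrast for tfpi2 (difference 7.39), marcksl1b (6.37), m17 (6.03), tmsb1 (5.94) and fpr1 (5.55). B cells had the higher one for hsp90aa1.2 (-5.54), zgc:194275 (-4.96), id3 (-4.85), gpr184 (-4.73) and TMCC3 (-4.52).

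Removal of the empty-droplet profile left a median of 90.9% (quartiles 71.2% and 109%) of the size of the class difference over 5854 called genes tested again, and 5747 of them had the same sign. That median argues against empty-droplet RNA as the whole cause. Thinning the class sums to the lowest total left a median of 99.1%, with 3658 of the 5893 calls kept in the same direction. Thinning draws all genes of a class sum at 1 rate and keeps expected ratios, so the size left cannot decide on depth. After removal 1525 of the 5893 calls remained. Over the called genes the median SE went from 0.332 to 0.432 and the median size from 1.68 to 1.47. The SE is derived from the F of the same test, so it does not explain the lost calls. TMCC3 went from -4.52 ± 0.48 to -1.90 ± 0.81 (SE, edgeR adjusted p = 0.217), with both a smaller difference and a larger SE. Differences in biology between the classes, in the kinds of granulocytes that the density gradient takes and in reads shared between paralogs stay open and untested.

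Markers of endothelial, stromal and interrenal cells were higher in nuclei within B cells and granulocytes, and RNA of empty droplets may account for a large part of this. After removal of the empty-droplet profile 43.9% of these calls stayed (46.8% in B cells, 41.0% in granulocytes), against 63.4% and 61.8% of all other genes higher in nuclei. Removal took 82.1% and 75.2% of their counts in B cell nuclei of replicates 3 and 9 and 76.0% and 72.5% in granulocyte nuclei, against 27.2% to 41.4% for the other genes. In B cells and granulocytes 21 and 30 of the markers fell under the expression filter. Of the markers still tested 70.7% and 80.6% stayed called, against 77.9% and 80.6% of the other genes still tested. In granulocytes the lower share kept over all calls thus came from markers that fell under the filter. The endothelial median went from -2.95 ± 2.62 to -2.05 ± 2.21 in B cells and from -4.78 ± 2.71 to -3.98 ± 2.43 in granulocytes (SD over the same genes). Doublets are argued against, since at most 1.01% of the UMIs of these markers over the 3 lists together, and at most 3.59% for any 1 list, came from nuclei with at least 50% of the level of the class they belong to, and B cell and granulocyte nuclei had almost the same mean, 5.32 and 5.54 endothelial UMIs in replicate 3 and 2.80 and 2.84 in replicate 9. Expression in the blood cells themselves stays open for the genes that remained, and no biological explanation was tested.

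Immediate early genes were higher in cells, with a median log2 difference of 3.36 over all called barcodes. A change in class makeup is argued against as the whole cause, since the lowest median within any of the 7 classes was 1.11, in NK or cytotoxic cells, although with class totals in place of TMM erythroid cells had -0.29 and the other 6 classes from 0.66 to 2.09. Free RNA in the cell suspension is argued against as the whole cause, since removal of the empty-droplet profile took 1.82% and 1.40% of the list's counts in the cell libraries (32.1% and 27.2% in the nucleus libraries) and left 109% of the median, from 3.36 ± 2.04 to 3.65 ± 2.07 (SD over 66 genes), while the list's share of UMIs in empty droplets, 0.703 and 0.754 of that in called cells, lay between the limits set in advance and decided nothing. Handling of fresh cells before lysis may also raise these genes, and it cannot be told apart from the other differences because method, tissue state, density gradient, sequencer and the PBS in the titles of the nuclei go together. No biological explanation was tested.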

How the results depend on the processing

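The removal of the empty-droplet profile, leaving out clusters mostly of 1 library, leaving out unnamed clusters, the doublet score limit of 0.65 and library totals in place of TMM were chosen after the data were examined. The other alternatives were planned. No paired analysis was possible because the groups share only 1 number. Leaving out 1 library assumes that the lone sample varies like the other group. Uniquely mapped reads could be used in 3 libraries only, and lists of abundant genes have no value where those genes are left out. RLE size factors moved the median log2 difference of all genes by less than 0.1 in each comparison. For 148 counts of genes across comparisons and alternatives the value stayed within 1.5 times, for 21 it was lower and for 6 higher. Named genes kept their side of the threshold in 4748 cases, lost the call in 170, gained one in 78 and turned, with a call in either fit, in 13. A sign that changed with no call in either fit counts as kept. Single lists kept their side in 1325 cases, with 159 calls lost, 77 of them with an estimated correlation and 41 with fry, and 52 gained. For lists, direction was compared only where both fits passed. Where no reason is given below, the cause was not tested.

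DESeq2 called 4243 genes in plasma cells, 1408 in NK or cytotoxic cells and 3379 for the class difference. Uniquely mapped reads gave 7773 genes in B cells, 5095 in plasma cells and 1486 in NK or cytotoxic cells, with 1 library fewer. Thinning to the lowest total, which lowers counts, gave 3740 in plasma cells, 2129 in T cells and 3845 for the class difference, so depth limits these counts. Leiden resolution 2 gave 4115 in NK or cytotoxic cells. Removal of the empty-droplet profile gave 1562 for the class difference. With 1 library left out, which leaves fewer samples, counts ranged from 7528 to 11482 in B cells, 8962 to 13200 in mononuclear phagocytes, 240 to 4360 in T cells, 0 to 2414 in erythroid cells (edgeR, 2911 at an unadjusted p under 0.05 where it was 0), 1133 to 3135 in NK or cytotoxic cells and 3488 to 6006 for the class difference. The chemokine CCL19 turned in mononuclear phagocytes without nucleus replicate 9, to 1.12, and its range with 1 library left out was from -0.88 to 1.12.

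Library or class totals in place of TMM moved the log2 differences toward nuclei in all called barcodes and in every class, by a median from -0.45 in NK or cytotoxic cells to -2.44 in erythroid cells. It gave 28436 genes over all called barcodes, 20815 in B cells, 11761 in plasma cells, 8601 in T cells and 11139 in erythroid cells, most of them higher in nuclei. Of named genes that passed on either scale, 12 turned: srrm1 (-0.31) and chd2 (-0.46) over all called barcodes, srrm1 (-0.18) and tnfaip2a (-0.26) in B cells, lgmn (-0.0766) and ddx5 (-0.26) in granulocytes, irf3 (-0.53) in plasma cells, and calr3b (-2.09), stat1a (-0.17), chd2 (-2.03), irf1-2 (-0.59) and tra2a (-1.48) in erythroid cells. Signs that changed without a call on either scale are not counted here. For the class difference it called 5798 genes.

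With an estimated correlation camera passed 0 lists in all called barcodes, 0 in B cells, 0 in granulocytes, 0 in mononuclear phagocytes, 0 in plasma cells, 0 in T cells, 0 in erythroid cells and 0 in NK or cytotoxic cells, with 1 list at an unadjusted p under 0.05 in B cells, 2 in plasma cells and 0 elsewhere. The fry test passed 6 lists in all called barcodes, 5 in granulocytes, 0 in T cells, 0 in erythroid cells and 0 in NK or cytotoxic cells (6, 5 and 5 lists at an unadjusted p under 0.05 in these last 3 classes). In simulated data fry also missed a 2-fold list in erythroid and NK or cytotoxic cells (fry adjusted p = 0.220 and 0.124), but not in T cells (0.0436). With abundant genes left out 5 lists passed in granulocytes, where 2 lists then have no value.

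The UMI limit moved many shares, since a lower limit calls many more nuclei that stay unnamed, while clustering moved progenitors and dendritic cells more. At 500 UMIs the differences in percentage points, cells minus nuclei, were 22.1 for B cells, 1.39 for NK or cytotoxic cells, -0.875 for T cells, -0.0892 for dendritic cells, -1.18 for endothelium, -0.716 for erythroid cells, -0.281 for progenitors, -0.514 for interrenal cells, -0.0783 for kidney tubule, 4.55 for mononuclear phagocytes, 2.83 for plasma cells, -0.286 for stroma, -0.0687 for thrombocytes and -68.3 for unnamed barcodes. At 1000 UMIs they were -4.64 for T cells, -0.249 for dendritic cells, -3.10 for endothelium, -0.775 for progenitors, -0.950 for interrenal cells, -0.193 for kidney tubule, 2.03 for mononuclear phagocytes, -0.674 for stroma, -0.936 for thrombocytes and -46.5 for unnamed barcodes. Quality differences at 500 and 1000 UMIs were -55649.5 and -23728 called barcodes, 4940.75 and 4883.75 for median UMIs, 1542 and 1301 for median genes and -68.5 at both for genes after thinning. Ribosomal protein genes differed by 10.9 points at 500 UMIs, and uniquely mapped reads gave -177 for genes after thinning.

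Clustering choices moved small classes. With 4 libraries clustered together the differences were 0.0496 for dendritic cells and 2.06 for progenitors, both turned, and -5.55 for endothelium, -0.976 for interrenal cells, 0 for kidney tubule and -1.09 for stroma. Leiden resolution 0.5 gave -12.4 for T cells, 1.79 for progenitors (turned), -0.968 for interrenal cells and 0 for kidney tubule, and resolution 2 gave -2.30 for progenitors and -0.446 for kidney tubule. Doublets kept gave -6.97 for endothelium and -2.58 for thrombocytes. A mitochondrial limit of 10% gave -0.336 for kidney tubule, and the doublet score limit of 0.65, which leaves that cluster unnamed, gave 0. The 10% limit also gave 0.548 for mononuclear phagocytes in place of -2.27, a change within the spread of the libraries. Leaving out clusters mostly of 1 library gave 23.1 for granulocytes in place of 35.8, -2.67 for B cells in place of 4.79 and 0.209 for mononuclear phagocytes in place of -2.27, changes within the spread of the libraries. It also gave -7.46 for endothelium, -1.97 for progenitors, -0.461 for kidney tubule, 3.05 for plasma cells, -1.72 for stroma and -2.64 for thrombocytes. For unnamed barcodes it gave 6.10 (turned), since the mean unnamed share fell in nuclei and also rose in cells.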

Other observations

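Clusters inside the named classes differed in their marker genes, given here as descriptions chosen after their values were seen, without a test. Nuclear T cells formed 3 clusters. The 1194 nuclei of the first had cd4-1, the coreceptor of helper T cells, among their leading genes, and the 677 nuclei of the second had cd8a, the coreceptor of cytotoxic T cells. The third, with 172 and 177 nuclei of replicates 3 and 9, was led by foxp3b, known from regulatory T cells, with tox and ikzf4, and had the inhibitory receptor CTLA4 among its markers. Single cells formed 1 named T cell cluster of 171 barcodes, with cd4-1, cd8a and foxp3b all among its markers. A second cluster of 232 cells, unnamed because its NK or cytotoxic score was 0.971 of its T cell score, had cd3e, BCL11B, tcf7, gata3, zap70, itk, CD247 and lck among its markers. B cells with the recombination genes rag1 or rag2 among their markers formed 4 clusters of cells (355, 310, 228 and 183 barcodes) and 2 clusters of nuclei (615 and 319 barcodes), and dntt, which adds bases at antigen receptor joints, led 3 of these 6 clusters. Granulocytes included clusters of 581 and 257 cells led by genes of the cell cycle, such as tyms, tk1, cdk1 and ccnb1. A further granulocyte cluster of 1171 cells had ifit9 and isg15 among their leading genes.

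Unnamed clusters held some barcodes with clear markers of their own. A cluster of 58 and 17 cells and a cluster of 41 and 57 nuclei both had GATA2 among their leading genes, a factor of blood progenitors and mast cells, and neither met the naming rule. A cluster of 468 cells had the progenitor genes HLF, fli1a, GFI1, tal1 and MYB among its markers and the platelet receptor mpl among its leading genes. The share of hemoglobin UMIs outside the erythroid class was 0.0462% and 0.0237% in cells and 0.0594% and 0.0555% in nuclei. In empty droplets it was 1.81% and 1.30% in the cell libraries and 0.128% and 0.165% in the nucleus libraries. Another unnamed cluster of 267 and 721 nuclei had correlations across genes with the empty droplets of its libraries of 0.952 and 0.969, where genes are not independent replicates, and ribosomal protein genes among its leading genes.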
